A study of Mus musculus with 4 samples.

How the data were processed

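RNA from the murine microglial cell line N9 was measured on 4 Affymetrix arrays. The cultures had received vehicle (2 arrays), 10 µM nimodipine (1 array) or 20 µM nimodipine (1 array). Per the labels, total RNA was isolated with TRIzol and labelled with the Affymetrix WT PLUS kit. The deposited values are log2 expression per probe set; per the submitters' processing notes they were made with Affymetrix Expression Console 1.2.1.20 and RMA. RMA corrects the background, sets the arrays to a common distribution by quantile normalization and summarises probes by median polish, so a shift shared by most genes would not be visible. The median of all deposited log2 values was 5.04, and the medians of the 4 arrays lay between 5.02 and 5.06. The number of arrays limits the precision. The deposited values carry no detection call, so folds of genes near background can be too small.

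The table held 41345 probe sets. The array annotation gave exactly 1 gene symbol to 23521 of them and several symbols to 1814, and it did not list 16010. Of the probe sets with 1 symbol, 23328 had an Entrez identifier in the RefSeq gene table (GRCm38.p6), which was used for names only, and 0 symbols needed updating. Where a gene had several probe sets, the one with the highest mean over the 4 arrays was taken, which left 22180 genes. Of the 1082 genes with more than 1 probe set, 454 had probe sets that differed in the sign of the difference between nimodipine and vehicle. Probe sets outside this selection entered only the alternatives that take all probe sets or the mean of a gene's probe sets, and, for those unlisted or with several symbols, a count.

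Nimodipine was compared with vehicle by limma (version 3.58.1, R 4.3.3; lmFit and eBayes with default settings), 2 arrays against 2, with Benjamini-Hochberg adjustment over 22180 genes and a threshold of 0.05. The spread within the nimodipine group includes the difference between the doses. Each dose had 1 array, so its log2 difference from the mean of the vehicle arrays was not tested in the main comparison; genes past a difference of 1 on the log2 scale were counted beside the same count for vehicle 2 against vehicle 1. The labels do not say that the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. They speak of a respective vehicle but do not say which vehicle array belongs to which dose. If each dose had its own vehicle, the vehicle arrays would not be plain replicates. Their difference would then include any difference between the vehicles.

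Before the data were examined, 41 gene lists were fixed, 40 by name and 1 by a rule on the symbols of small nucleolar RNAs and microRNAs. Of the 850 members fixed by name, summed over lists, 755 were measured. Lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over the 41 lists. camera with an estimated correlation and fry were alternatives. For each dose, a list's median difference was placed among 10000 random lists of the same size, drawn from 50 bins of mean expression; this percentile describes the arrays and is no p-value.

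The genes named in the text followed a rule fixed at the same time. It took the 12 genes with the largest mean change each way among those past the threshold. A direction with fewer was filled with genes whose nimodipine arrays both lay beyond both vehicle arrays and whose mean was at or above the median of all probe sets, ranked by the smaller of the differences at the 2 doses. It further took up to 4 members of each list, by absolute mean difference, the pore-forming L-type channel genes Cacna1c, Cacna1d, Cacna1f and Cacna1s, and the 6 genes with the largest difference between the doses each way. Predicted genes, clone names, small RNAs and receptor-cluster families were passed over when genes were ranked, so they do not appear among the genes that lead a ranking.

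The alternatives were a filter on dim probe sets (mean at or above the median), all probe sets, the mean of a gene's probe sets, equal array medians, cyclic loess, eBayes with a trend or robust, other thresholds, dose as a number, 3 groups, separate vehicle arrays for the doses, and leaving out each array in turn. The contrasts of each dose alone and of the doses in the fit of 3 groups, and separate vehicle arrays for counts of genes shared by the doses, were added after seeing the data. Because both doses were compared with the same vehicle arrays, their covariance across genes was set beside 20 simulations of unchanged arrays. Simulated data for the 2 against 2 comparison of 22180 genes had 200 genes changed alike on both nimodipine arrays. There limma recovered 0% of changes of 1 on the log2 scale, 96.5% of changes of 2 and 99.5% of changes of 4. A change at 1 dose only, which widens the spread within the nimodipine group, was not simulated, so these rates do not apply to it. A glycolysis list shifted by -0.5 in simulated data was called, with 0 of the other lists called. The simulated genes were independent, while the correlation estimated for the glycolysis list in the real arrays was 0.738. The simulation therefore does not show how camera behaves for correlated lists. Scripts ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.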

Results

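The series profiled gene expression in N9 cells, an immortalised line of mouse microglia, after exposure to nimodipine, a dihydropyridine that blocks L-type voltage-gated calcium channels. Its title asks about the role of dihydropyridines in murine microglia. There were 4 arrays, with 2 from vehicle-treated cells, 1 from cells at 10 µM and 1 from cells at 20 µM, and 22180 genes were compared. Each dose had no replicate.

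Ddit3, Trib3 and Car6 had their highest values on the 10 µM array, and Egln3, Adm and Slc2a1 their lowest. At 10 µM, 348 genes differed from the vehicle mean by 1 or more on the log2 scale, 114 of them higher and 234 lower. At 20 µM the count was 19, with 8 higher and 11 lower, and between the vehicle arrays it was 25. With dim probe sets left out, the counts were 14 at 20 µM and 5 between the vehicle arrays. The dose counts set 1 array against a mean of 2, whereas the vehicle count sets 1 array against 1. Array against array, the 10 µM array had 378 such genes against vehicle 1 and 407 against vehicle 2. The 20 µM array had 38 and 37, beside the 25 between the vehicle arrays. With nimodipine taken as 1 group, limma called 0 genes, the smallest adjusted p being 0.792. At an unadjusted p under 0.05 there were 1191 genes, 531 higher and 660 lower, beside 1109 given by chance. Both nimodipine arrays lay above both vehicle arrays for 4253 genes and below both for 4043, together 37.4% of genes against 33.3% by chance. In the fit of 3 groups, the contrasts of single doses were added after seeing the data and assume that a lone array varies like the vehicle pair (residual df 1). limma then called 353 genes at 10 µM, and 0 at 20 µM, where 1418 genes had an unadjusted p under 0.05.

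**Figure D1:**
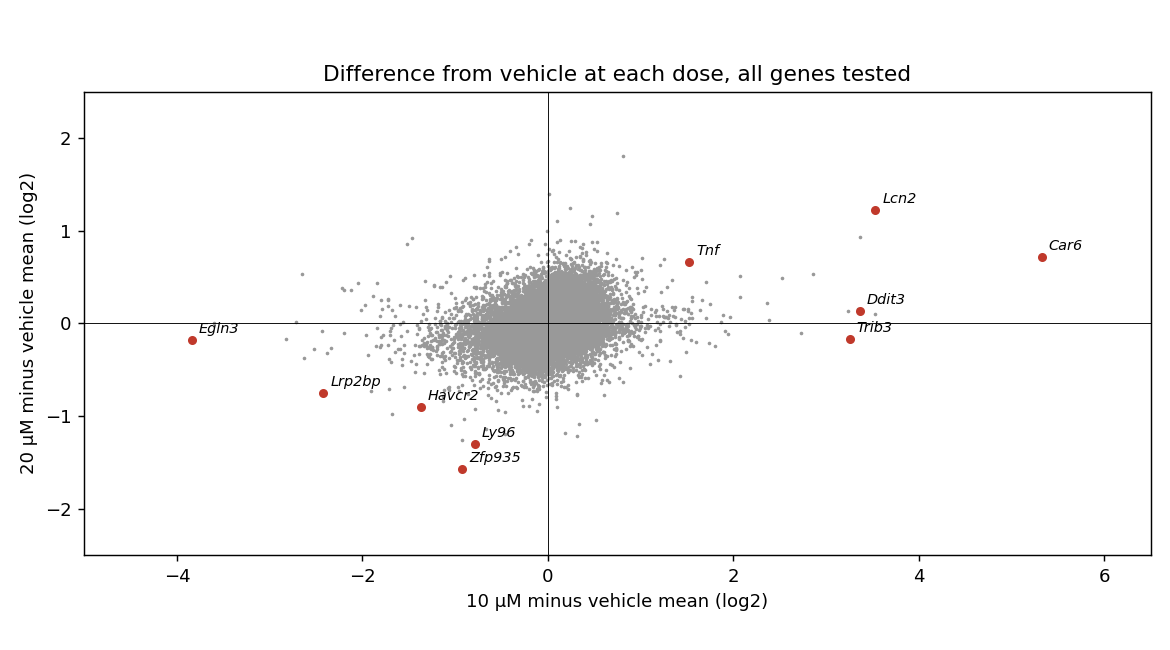
Each grey point is 1 of the 22180 genes, with its log2 difference from the vehicle mean at 10 µM on the horizontal axis and at 20 µM on the vertical axis; red points are named genes. The cloud is wider along the 10 µM axis (SD 0.341) than along the 20 µM axis (SD 0.214).

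The 27 measured G2/M and mitosis genes fell as a list in nimodipine against vehicle, with a median difference of -0.60 (camera, adjusted p = 9.49e-11). The adjusted p was 0.84 with an estimated correlation. At 10 µM all 27 were lower than the vehicle mean, 16 of them by 1 or more on the log2 scale, with a median of -1.07. At 20 µM 22 of 27 were lower, with a median of -0.12, at percentile 1.46 of random lists. The same genes were higher in vehicle 2 than in vehicle 1, with a median difference of 0.15, at percentile 100.0 of random lists. Kif11, a kinesin motor of the mitotic spindle, was 2.71-fold lower at 10 µM and 1.18-fold lower at 20 µM. Plk1 and Aurkb, kinases of mitosis, were 2.40-fold and 2.16-fold lower at 10 µM. Ccnb2, a mitotic cyclin, differed by -0.47 at 20 µM on the log2 scale, and its vehicle arrays differed by 0.36. The 28 genes of G1/S and DNA replication had medians of -0.22 and 0.00 at the lower and the higher dose and missed the threshold (adjusted p = 0.0765, and 0.0110 without vehicle 1 or 0.0137 without the 20 µM array); Mcm7 was 1.69-fold lower and Mcm2 1.92-fold higher at 10 µM.

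The 30 targets of the integrated stress response and ATF4 rose as a list (median 0.40, camera adjusted p = 4.71e-05), and the adjusted p was 0.84 with an estimated correlation. At 10 µM 26 of 30 were higher, 11 by 1 or more, with a median of 0.79; at 20 µM 15 were higher and 15 lower, with a median of 0.01. Ddit3, which encodes the stress transcription factor CHOP, stood at 7.32 and 7.24 in the vehicle arrays, 10.64 at 10 µM and 7.41 at 20 µM. Trib3, a pseudokinase induced by ATF4 and CHOP, was 9.54-fold higher at 10 µM and 1.12-fold lower at 20 µM. Aldh1l2, a mitochondrial enzyme of folate metabolism, was 4.21-fold higher at 10 µM. Ddit4, an inhibitor of mTORC1 signalling, went the other way and was 4.58-fold lower. The 20 endoplasmic reticulum chaperone and unfolded protein response genes also rose as a list (median 0.19, adjusted p = 0.0369), with an adjusted p of 0.84 with an estimated correlation. Of these, 17 were higher and 3 lower at 10 µM, and 14 and 6 at 20 µM. Hspa5, the main chaperone of that compartment, was 2.35-fold higher at 10 µM and 1.14-fold higher at 20 µM, and Herpud1 was 2.80-fold higher and 1.02-fold lower. Without vehicle 1 or vehicle 2 the chaperone list had medians of 0.18 and 0.19 (adjusted p = 0.0967 and 0.130), and without the 10 µM array the median was 0.05 (adjusted p = 0.880).

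The 16 hypoxia targets and the 17 glycolysis genes fell as lists, with medians of -0.37 and -0.28 (camera adjusted p = 2.68e-04 and 1.00e-04). The adjusted p of each was 0.84 with an estimated correlation. At 10 µM 13 of 16 hypoxia targets and 16 of 17 glycolysis genes were lower, with medians of -0.59 and -0.55. At 20 µM 14 of 16 hypoxia targets were lower with a median of -0.15, while the vehicle arrays differed by -0.14; the glycolysis median at 20 µM was -0.04. Egln3, an oxygen-sensing prolyl hydroxylase, stood at 8.35 and 8.91 in the vehicle arrays, 4.79 at 10 µM and 8.45 at 20 µM. Adm, which encodes adrenomedullin, stood at 8.61 and 8.45, then 4.93 and 8.53. Their values at 10 µM lay below the median of all values (5.04), so no fold is given. The glucose transporter Slc2a1, hexokinase Hk2, pyruvate dehydrogenase kinase Pdk1 and lactate transporter Slc16a3 were 3.43-fold, 3.23-fold, 2.43-fold and 2.15-fold lower at 10 µM. Slc2a1 is in both lists.

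The 20 genes of cholesterol biosynthesis rose as a list (median 0.16, camera adjusted p = 0.0390), with an adjusted p of 0.84 with an estimated correlation. The medians were 0.14 at 10 µM (14 higher, 6 lower) and 0.17 at 20 µM (15 higher, 5 lower), and the vehicle arrays differed by 0.20 in the same genes. Hsd17b7 was higher by 0.42 ± 0.16 (limma SE, 2 arrays per group) on the log2 scale and Hmgcs1 by 0.30 ± 0.19, while Pmvk, also of this pathway, differed by -0.44 ± 0.22. Without vehicle 1 the list's median was 0.07 (adjusted p = 0.530). Without the 10 µM array it was 0.17 (adjusted p = 0.187) and without the 20 µM array 0.14 (adjusted p = 0.164).

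For all 6 of these lists, 0 members passed the adjusted threshold over all genes, and 0 did when adjusted over the list alone. camera called 0 of 41 lists without the 10 µM array and 11 without the 20 µM array. Without the 10 µM array the median was -0.12 for G2/M genes, 0.01 for ATF4 targets, -0.15 for hypoxia targets, -0.04 for glycolysis, 0.05 for chaperones and 0.17 for cholesterol biosynthesis.

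**Figure D2:**
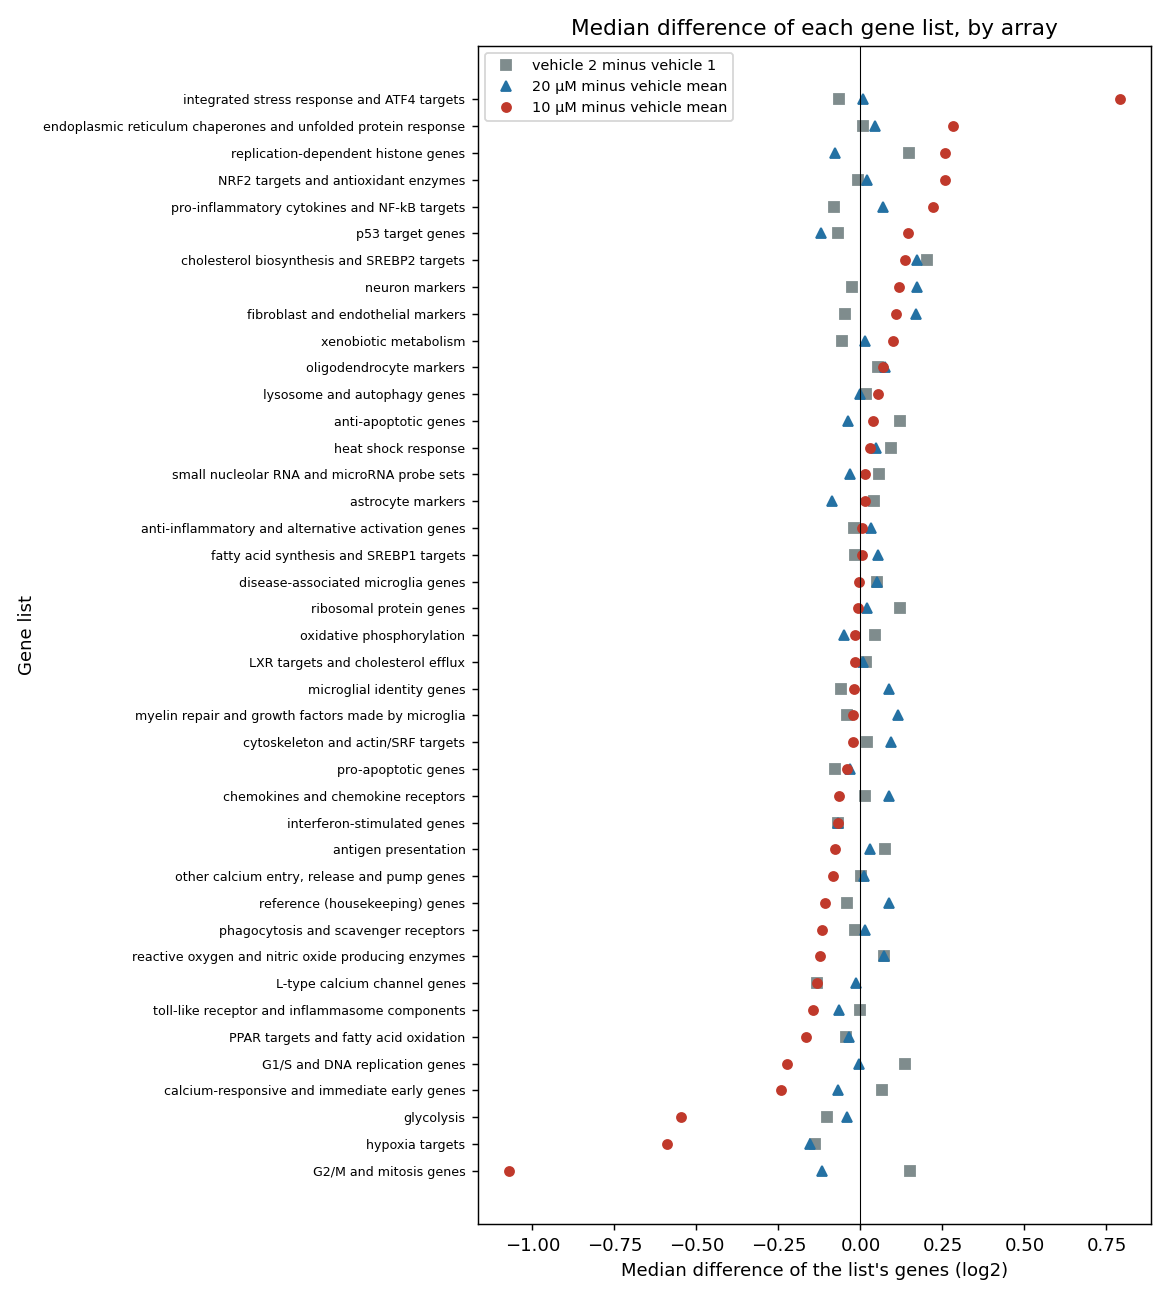
Each row is 1 of the 41 gene lists, and the horizontal axis gives the median log2 difference of its genes for 10 µM minus the vehicle mean (circles), 20 µM minus the vehicle mean (triangles) and vehicle 2 minus vehicle 1 (squares). The 10 µM medians run from -1.07 for G2/M genes to 0.79 for ATF4 targets, while the 20 µM medians run from -0.15 to 0.17.

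Of the 11 measured L-type channel subunit genes, the drug's target class, 9 were lower at 10 µM and 6 at 20 µM, and the list was not called (median -0.06, camera adjusted p = 0.566). The median was -0.13 at 10 µM, at percentile 1.44 of random lists, and -0.01 at 20 µM, and the vehicle arrays differed by -0.13 in the same genes. The list's median level over the arrays was 4.74, and only 4 of the 11 genes had a mean at or above the median of all values. Its counts and percentile therefore rest mostly on dim probe sets. With these left out, the median for nimodipine against vehicle was -0.18, and the list was too small to test. Cacna1c, the pore-forming subunit of the Cav1.2 channel, stood at 4.68 and 4.44 in the vehicle arrays, 4.48 at 10 µM and 4.59 at 20 µM, all below the median of all values. Cacna1d was lower by -0.46 ± 0.16 (SE), below both vehicle arrays at both doses, with a limma adjusted p of 0.792. Cacna1f and Cacna1s differed by -0.06 ± 0.12 and 0.05 ± 0.12. Among 25 other calcium entry, release and pump genes (adjusted p = 0.447), Orai3, a subunit of store-operated calcium channels, was 1.46-fold lower at 10 µM and 1.54-fold lower at 20 µM. Calcium-responsive and immediate early genes (19 measured) had a median of -0.24 at 10 µM and -0.07 at 20 µM and missed the threshold (adjusted p = 0.122). The 10 µM median lay at percentile 0.32 of random lists, and without the 20 µM array the adjusted p was 0.00158. Ier3, Rcan1 and Nr4a1 were 3.31-fold, 3.26-fold and 2.67-fold lower at 10 µM.

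None of the inflammatory lists was called with all 4 arrays and all 22180 genes. The 25 pro-inflammatory cytokine and NF-kB genes had medians of 0.22 at 10 µM and 0.07 at 20 µM (adjusted p = 0.111), the former at percentile 99.99 of random lists. The adjusted p was 0.0336 with dim probe sets left out and 0.0116 without the 20 µM array. Lcn2, which encodes lipocalin 2, was 11.5-fold higher at 10 µM and 2.34-fold higher at 20 µM, and Tnf was 2.88-fold and 1.59-fold higher. Il23a was 5.21-fold higher and Il1b 2.68-fold lower at 10 µM. Toll-like receptor and inflammasome genes (25) had medians of -0.15 and -0.07 (adjusted p = 0.111), with Tlr6 3.28-fold lower at 10 µM and 1.63-fold at 20 µM, and Ly96, the co-receptor of Tlr4, 1.73-fold and 2.46-fold lower. Nos2, the inducible nitric oxide synthase, was 2.42-fold lower at 10 µM and 1.21-fold lower at 20 µM, in a list of oxidant-producing enzymes with an adjusted p of 0.819. Interferon-stimulated genes (adjusted p = 0.410, and 0.0336 with a median of -0.24 when dim probe sets were left out), chemokines and their receptors (0.819), alternative activation genes (0.861) and antigen presentation genes (0.819) were not called. Fcgr1, an immunoglobulin receptor, was 5.17-fold higher and Clec7a 3.19-fold lower at 10 µM among phagocytosis genes (adjusted p = 0.414, and 0.0274 without the 20 µM array). Microglial identity genes (0.861), disease-associated microglia genes (0.819) and growth factors of myelin repair (0.531) had 10 µM medians of -0.02, -0.01 and -0.02 and 20 µM medians of 0.09, 0.05 and 0.11.

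Among the other lists, NRF2 targets and antioxidant enzymes had a median of 0.26 at 10 µM, at percentile 99.99 of random lists, and 0.02 at 20 µM (camera adjusted p = 0.111, and 0.0336 with dim probe sets left out, 0.0293 with loess or 0.00218 without the 20 µM array). Outside the central 95% of random lists lay 12 of the 41 lists at 10 µM, 6 at 20 µM and 9 between the vehicle arrays. For lists of independent genes, 2.05 would be expected. Members of a real list can move together (estimated correlation 0.899 for G2/M genes), so 2.05 may be too low for these lists. Among the NRF2 targets, Gsta3 was 2.53-fold higher and Hmox1 1.70-fold lower at 10 µM. Pro-apoptotic (adjusted p = 0.688), anti-apoptotic (0.819) and p53 target genes (0.845) were not called, although Fas was 3.36-fold and Bcl2 2.95-fold higher at 10 µM, and Cdkn1a, the cell-cycle inhibitor p21, 1.67-fold and 1.46-fold lower at the respective doses. Heat shock genes (0.819), fatty acid synthesis (0.549), LXR targets (0.933), PPAR targets and fatty acid oxidation (0.410), xenobiotic metabolism (0.566), lysosome and autophagy (0.781), oxidative phosphorylation (0.802), ribosomal proteins (0.819), cytoskeleton (0.819), histones (0.688, and 0.0208 without the 20 µM array) and reference genes (0.955) had adjusted p values above the threshold with all arrays. Sqstm1, an autophagy receptor, was 2.84-fold higher and Cpt1a, which carries fatty acids into mitochondria, 2.24-fold lower at 10 µM. Markers of other cell types were not called either: astrocytes (adjusted p = 0.775), neurons (0.140), oligodendrocytes (0.688), and fibroblasts and endothelium (0.111, and 0.0399 with dim probe sets left out), the last with medians of 0.11 and 0.17 at the lower and the higher dose. Small nucleolar RNA and microRNA probe sets (557, adjusted p = 0.845) had medians of 0.01 and -0.03, and 0.06 between the vehicle arrays. With dim probe sets left out the direction of this list turned, from a median of -0.01 for nimodipine against vehicle to 0.07 (adjusted p = 0.00358).

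**Figure D3:**
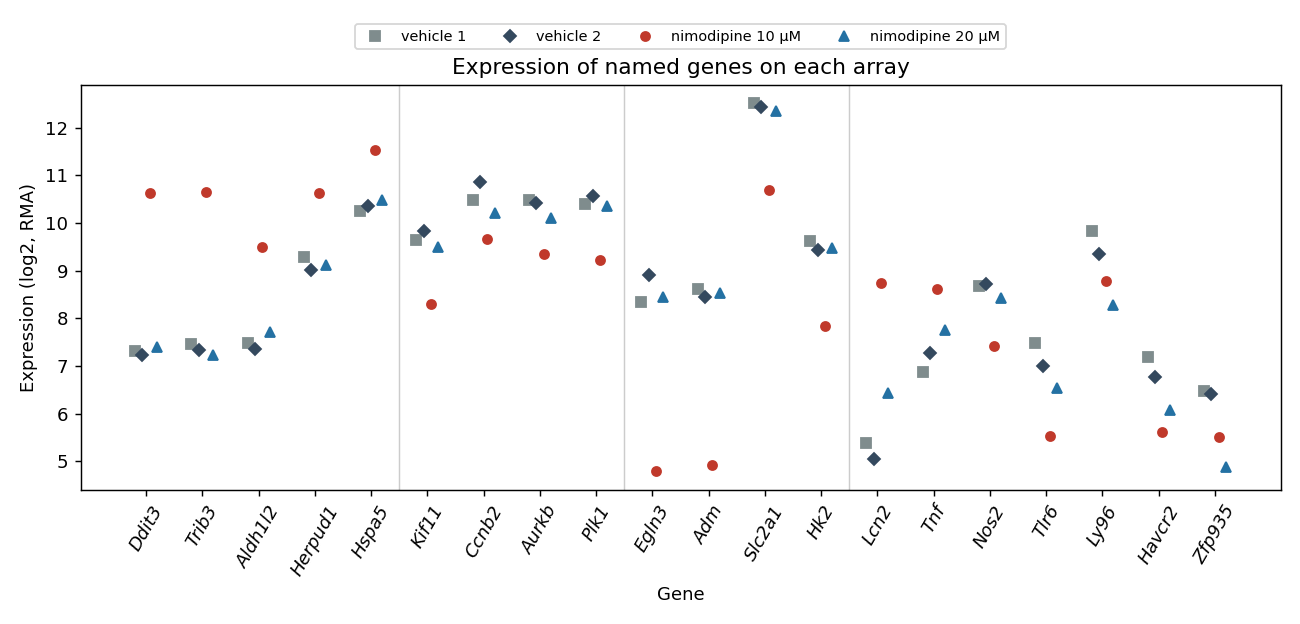
Each point is 1 array's log2 RMA expression of 1 named gene; squares and diamonds are the vehicle arrays, circles 10 µM and triangles 20 µM nimodipine. Ddit3 and Trib3 stand at 10.64 and 10.65 at 10 µM and between 7.23 and 7.46 on the other arrays, and Egln3 and Adm stand at 4.79 and 4.93 at 10 µM and between 8.35 and 8.91 elsewhere.

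With small RNAs, predicted genes and the like passed over, genes beyond both vehicle arrays at both doses were led on the high side by Lcn2, Car6, Plk2, Oxct2b and Tnf, followed by Derl3, Ckmt1, Corin, Ppib, Mob3c, Col8a2 and Ift22. None passed the test (limma adjusted p = 0.792 for each). Car6, a secreted carbonic anhydrase, stood at 4.33 and 4.50 in the vehicle arrays, below the median of all values, 9.74 at 10 µM and 5.13 at 20 µM. Both vehicle values also lay below that median for Oxct2b (4.64 and 4.77), Ckmt1 (4.45 and 5.01) and Col8a2 (4.85 and 4.89). The vehicle arrays differed by 0.56 for Ckmt1 and -0.47 for Corin, beside differences of 0.63 and 0.61 at 20 µM. Plk2 was higher by 0.98 ± 0.24 (SE) and Ppib, an endoplasmic reticulum cyclophilin, by 0.58 ± 0.13 on the log2 scale. On the low side, Zfp935 stood at 6.48 and 6.41 in the vehicle arrays, 5.52 at 10 µM and 4.87 at 20 µM, the last below the median of all values. Zfp942 was 1.88-fold and 2.05-fold lower, and Havcr2, which encodes the inhibitory receptor TIM-3, 2.59-fold and 1.87-fold. Ly96, Abhd18, Lrp2bp, Frrs1l, Pde7b, Tlr6, Vps33b, Abca9 and Map2k6 made up the rest, with the same adjusted p. For Abhd18 the vehicle arrays differed by -0.845, beside -0.861 at 10 µM and -0.766 at 20 µM. Lrp2bp was 5.35-fold lower at 10 µM and 1.69-fold at 20 µM.

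Between the doses, 363 genes differed by 1 or more on the log2 scale, 213 higher at 20 µM and 150 lower, beside 25 between the vehicle arrays. The contrast of the doses in the fit of 3 groups, added after seeing the data, called 38 genes higher at 20 µM and 32 lower (smallest limma adjusted p = 0.00655, residual df 1), on the same assumption about lone arrays. The genes furthest above at 20 µM were Egln3, Adm, Serpinb1a, Il10ra, Cytip and C3ar1, each lower than vehicle at 10 µM by 4.66-fold or more. Il10ra, a chain of the interleukin-10 receptor, was 6.57-fold lower at 10 µM and 1.01-fold higher at 20 µM. The genes furthest above at 10 µM were Car6, Cox6a2, Trib3, Ddit3, Gbp8 and Cth. Cox6a2, a subunit of cytochrome c oxidase, was 11.5-fold higher at 10 µM and differed by 0.11 on the log2 scale at 20 µM. Cth, an enzyme of cysteine synthesis, was 9.42-fold and 1.10-fold higher. With a separate vehicle array for each dose, added after seeing the data, 58.5% or 51.1% of the genes higher by 1 or more at 10 µM were higher at 20 µM, beside 48.8% or 50.5% of all genes. Of the genes lower at 10 µM, 71.0% or 63.4% were lower at 20 µM, beside 51.1% or 49.3%. Against the mean of both vehicle arrays, Lcn2 was the only gene past 1 on the high side at both doses, and 1 predicted gene was on the low side. Independent lists would share 0.0411 and 0.116 genes, and simulated unchanged arrays with the same vehicle pair shared 2.70 and 2.30 on average. Across genes, the covariance of the differences at the doses was 0.0205 (r = 0.280). For simulated unchanged arrays that share the vehicle pair it was 0.0141 (r = 0.338), a difference of 0.00641. The simulated arrays all had the spread of the vehicle pair, while the real differences were wider at 10 µM (SD 0.341) than at 20 µM (SD 0.214). The r values are therefore not comparable. With a separate vehicle array for each dose the covariance was 0.00919 or 0.00612. These are values across genes, which are not independent replicates.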

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

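The contrasts of single doses and between doses in the fit of 3 groups were added after seeing the data. For nimodipine against vehicle, limma's count of 0 genes (1191 at an unadjusted p under 0.05) stayed 0 under every filter, scaling, moderation and threshold tried, under dose as a number, and without either vehicle array. It was 12 for the mean of the dose contrasts in 3 groups, 353 for the 10 µM contrast alone, and 0 to 353 over the leave-one-out fits, the 353 being without the 20 µM array; the lone array is then assumed to vary like the vehicle pair. At 1.5-fold the counts against the vehicle mean were 1539 genes at 10 µM and 284 at 20 µM. Array against array, they were 1729 between doses and 434 between the vehicle arrays. The contrast of the doses in 3 groups called 70 genes. With dim probe sets left out, the vehicle pair had 5 genes and 20 µM had 14, against 25 and 19 before, so their order turned. Against single vehicle arrays the 20 µM count was 37 to 38. Separate vehicle arrays gave covariances of 0.00919 and 0.00612, since the shared part is then removed. Called lists numbered 6 in the main test, 0 with an estimated correlation, 0 with fry and 11 with dim probe sets left out. The 2 camera runs differ in the correlation and in the degrees of freedom, which fall to the residual 2 when the correlation is estimated. So p also rose for lists whose estimate lay below the preset. For toll-like receptor genes (estimate -0.036), the unadjusted camera p went from 0.0284 to 0.135. Estimated correlations of the 6 called lists ran from 0.206 for cholesterol biosynthesis to 0.899 for G2/M genes, against the preset 0.01. Like the spread, these estimates include the difference between the doses. The cause of the other changes was not tested. Of the list values, 290 kept their side of the threshold, 22 lost it and 13 gained it (NRF2, NF-kB, interferon-stimulated, fibroblast and small RNA lists with dim probe sets left out; NRF2 with loess; G1/S without vehicle 1; immediate early, NRF2, NF-kB, phagocytosis, G1/S and histone lists without the 20 µM array; the small RNA list with its sign turned), and lists not called changed sign in 35 of 277 values. Among 181 named genes, 33 of 1966 values changed sign. The count was 0 among those chosen for lying beyond vehicle at both doses. That choice largely fixed this count in advance, since leaving out any 1 array cannot turn the sign of such a gene. Loess moved the median of all genes by -0.01 at 10 µM and 0.00 at 20 µM, equal array medians by -0.04 and -0.03. No paired analysis was possible because the labels number only the vehicle arrays. Genes near background, such as Cacna1c, Car6 in vehicle, Egln3 and Adm at 10 µM, and Zfp935 at 20 µM, are limited by their low signal.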

Other observations

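All tests of explanations in this part were chosen after the results were seen. Genes past 1 on the log2 scale at 20 µM and not at 10 µM were also looked at after their values were seen. Those given here are examples and not a full list. In all, 19 genes were past 1 at 20 µM from the vehicle mean, beside 25 between the vehicle arrays, array against array. Ppif, which encodes the mitochondrial cyclophilin D, stood at 9.51 and 9.51 in the vehicle arrays, 9.82 at 10 µM and 8.30 at 20 µM. Alg12, a mannosyltransferase of the endoplasmic reticulum, stood at 9.37 and 9.40, then 9.90 and 8.34. Tmem98 was at 7.67, 7.54, 7.93 and 6.52 in the same order. Nkain1 was at 7.91, 8.29, 8.20 and 9.21. None passed limma's test, and 1 array per dose gives no replicate check.

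The array at 10 µM stood apart from the other 3 arrays, with 348 genes past 1 on the log2 scale from the vehicle mean against 19 at 20 µM. Array against array, the 10 µM array had 378 and 407 such genes against vehicle 1 and vehicle 2. The 20 µM array had 38 and 37, beside 25 between the vehicle arrays. Quantile normalization moves values of one level alike, so it would not set genes apart from others of their level. With the median difference of genes at the same vehicle level removed, 332 genes were past 1 at 10 µM, 120 higher and 212 lower. Between the vehicle arrays, array against array, 24 were. These values argue against normalization as the source of the differences within a level. The medians removed lay only between -0.096 and 0.077, since RMA had already set the arrays to a common distribution. A shift shared by most genes of a level could not be seen this way and stays open. Exchanged dose labels stay open: the slope of the 20 µM on the 10 µM difference, with separate vehicle arrays, averaged 0.0596, too small for a scaled-down copy and not at or below 0. A culture state unrelated to the drug, such as density or oxygen, also stays open, since the hypoxia list was lower in vehicle 2 than in vehicle 1 (-0.14, percentile 0.12 of random lists), but G2/M genes, lower with it at 10 µM, were higher there (0.15), and 9 of 41 lists lay outside random lists between the vehicle arrays. An effect of 10 µM nimodipine stays open and untested, as 1 array per dose cannot part dose from culture.

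A set of 57 small RNAs had symbols starting with Snor or Rnu and a mean level of at least 8. It is not confined to small nucleolar RNAs and differs from the fixed list of small nucleolar RNAs and microRNAs. The set's median difference from the vehicle mean was 0.17 at 10 µM and 0.07 at 20 µM. Recovery of small RNA that varies from array to array is a candidate explanation: all 57 were higher in vehicle 2 than in vehicle 1, with a median of 0.308, beyond the central 95% of random lists. Snora75 stood at 8.43 and 8.90 in the vehicle arrays, 9.48 at 10 µM and 10.47 at 20 µM, past vehicle 2 at both doses. No biological explanation was tested.

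Zfp935 and Zfp942 led the named genes lower at both doses, so all 370 genes named Zfp and a digit were examined as a class. Their median was -0.09 at 10 µM, with 236 lower, and -0.072 at 20 µM, with 229 lower, both below the central 95% of random lists. A shift of the class with nimodipine may underlie this, but the vehicle arrays differed the same way (-0.04, percentile 0.18), so it cannot be told apart from variation between arrays.

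The other ways of pairing the arrays 2 against 2 gave 747 and 589 genes at an unadjusted p under 0.05, beside 1191 for nimodipine against vehicle, and 0 adjusted in each. Of the 17824 probe sets that were unlisted or had several symbols, 593 at 10 µM and 444 at 20 µM were past 1 on the log2 scale from the vehicle mean. Between the vehicle arrays, array against array, 604 were.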
